A study of Mus musculus with 9 samples.

How the data were processed

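Transcript levels were measured on Affymetrix MOE430A arrays in 3 structures microdissected from wild-type mouse kidneys at embryonic day 14.5 (Theiler stage 22), with 3 arrays per structure and 1 sample per array. Per the labels, each renal vesicle and each s-shaped body sample pooled 20 structures, each collecting duct sample had a pool size of 1, and the sex of the embryos was unknown. Per the labels' protocols, total RNA went through 2 rounds of T7-driven amplification before hybridization.

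The deposited values were intensity on a linear scale, 1 value per probe set and array. The submitters' processing notes name GCOS, the Affymetrix array software, without a version or an algorithm. The mean of each array without the top and bottom 2% of probe sets lay between 500.2 and 500.3, so the values had been scaled to a common mean, although no record states the target. Array medians lay between 112.2 and 144.8, no value was missing, and no detection calls were used. Arrays give no counts, so the number of arrays limits the precision.

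The table held 22690 probe sets, of which 64 were controls. The platform annotation of 2016 paired 20380 probe sets with exactly 1 gene symbol, 691 with several and 1555 with none, and the first set covered 12393 genes. Gene identifiers of 20351 of the 20380 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. The files name no genome build, and therefore no coordinates are given.

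A pseudocount of 26, the 20th percentile of all values, was added before taking log2. Array medians then differed by up to 0.31 log2 units, above the limit of 0.25 set for leaving them as they were, and the arrays were quantile normalized. Probe sets above the median of their own array in at least 3 arrays were kept, 11597 in all. Each gene was represented by the probe set with the highest mean over the 9 arrays, which left 7998 genes to test, 2491 of them chosen from several probe sets. The pseudocount shrinks the differences of dim genes, so their folds are understated.

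Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 9 arrays, with 6 residual degrees of freedom and without covariates. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 is called a change. The comparisons were renal vesicle against collecting duct, s-shaped body against collecting duct, and s-shaped body against renal vesicle. Further results were a moderated F test over the 3 structures, the genes higher in 1 structure than in each of the others, and the changes shared by both nephron structures. Because these last comparisons use the same collecting duct arrays, overlaps were set beside the number that independent calls would share. They were also set beside 100 simulations without differences, in which all 9 arrays were simulated and both comparisons shared the simulated collecting duct arrays.

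In total 24 gene lists were written from textbook knowledge: nephron induction, podocyte, proximal tubule, loop and distal tubule, Notch pathway, ureteric tip, collecting duct trunk, urothelium, cap mesenchyme, Hox genes, Wnt signalling, FGF and RET response, BMP and TGF-beta signalling, basement membrane, epithelial junctions, cell cycle, glycolysis and hypoxia, interstitium, endothelium, erythroid, macrophage, neural, immediate-early and stress, and sex-linked genes. The 21 lists with at least 5 measured members were tested in each comparison with camera at its preset inter-gene correlation of 0.01, adjusted over 63 tests, and again with a correlation estimated from the data and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. Some genes stand in several lists, so the list tests are not independent of each other.

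The comparisons, tests, alternatives, lists and the rule for naming genes were fixed before the data were examined. The rule named, in each comparison, the 10 strongest rises and the 10 strongest falls among changed genes whose groups did not overlap, up to 4 members of each list with the smallest adjusted p, a fixed set of anchor genes whatever their values, and the members of the lists for other cells and sample state. Alternatives were other pseudocounts, median centring or no further normalization, a stricter filter or none, other choices of probe set, no intensity trend, array weights, fitting only the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each array in turn. After the data were examined, replicate 3 as a batch and the joint omission of renal vesicle replicate 3 and collecting duct replicate 2 were added, as were 6 gene lists (imprinted genes, retinoic acid, guidance cues, cystic disease genes, epithelial regulators and mitochondrial respiration).

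The procedure was tested on simulated data for each comparison over 7998 genes. With a simulated change of 1 log2 unit it recovered 68.2% of changed genes for renal vesicle against collecting duct, 72.7% for s-shaped body against collecting duct and 72.7% for s-shaped body against renal vesicle. With a change of 2 log2 units the recovered percentages were 97, 98.5 and 98.5 in the same order, and with 0.5 they were 7.35, 8.82 and 10.3. False calls made up 3.39%, 4.8% and 2.44% of the calls. At each size only 66 to 68 genes were changed, with noise drawn independently for each gene. In the measured comparisons 31.5% to 36.3% of genes were called, so these rates need not hold there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.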

Results

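Transcript levels were compared between 3 structures of the embryonic mouse kidney. The renal vesicle is the first epithelial body of a nephron, formed when condensed mesenchyme turns into epithelium, and the s-shaped body is the later, folded stage in which glomerulus and tubule are laid out. The collecting duct is the branched drainage epithelium that grows from the ureteric bud, and the submitters chose it as the reference for both nephron stages. Each structure had 3 arrays, and 7998 genes were tested. The nephron samples were pools of 20 structures and the labels give the collecting duct samples a pool size of 1, so the spread between replicates is that between such samples. Deposited array medians ran from 112.2 to 144.8 intensity units.

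Arrays of the same structure resembled each other more than arrays of different structures. Across genes, which are not independent replicates, the correlation between 2 arrays was 0.939 to 0.982 within a structure and 0.77 to 0.868 between structures. The median gene had an SD of 0.19 log2 units in the renal vesicle, 0.19 in the s-shaped body and 0.26 in the collecting duct. At least 1 structure differed for 3965 genes (49.6%) by the F test. A 3'/5' signal ratio of Gapdh, which rises as RNA is shortened, was 20.0 to 32.4 in the s-shaped body and 11.6 to 18.6 in the collecting duct, with the renal vesicle inside the latter range. The same ratio of Actb overlapped between structures, at 30.1 to 50.9 in the s-shaped body and 34.1 to 42.5 in the collecting duct.

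**Figure D1:**
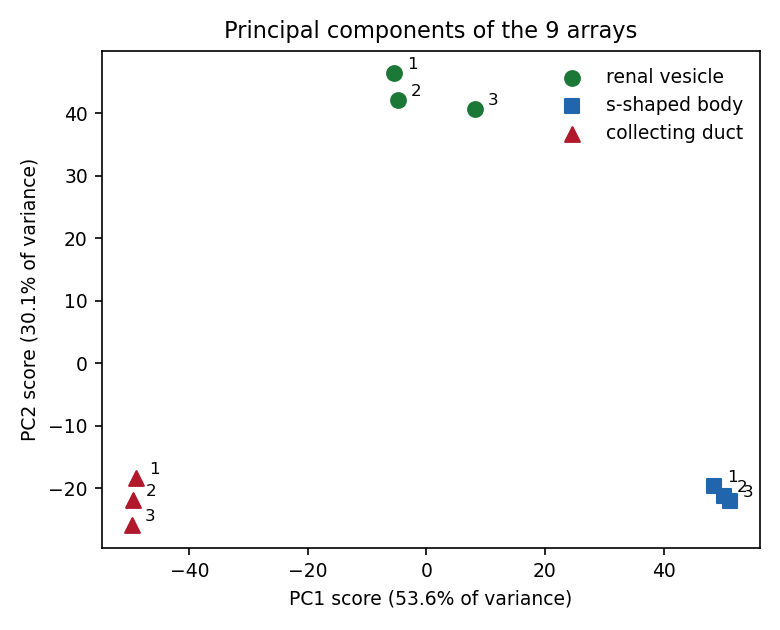
Position of the 9 arrays on the first 2 principal components of the 7998 log2 intensities, which hold 53.6% and 30.1% of the variance, with 1 point per array and 1 colour per structure. The 3 structures occupy separate regions, and renal vesicle replicate 3 lies apart from the other renal vesicle arrays.

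The comparison of renal vesicle with collecting duct asks which transcripts set the earliest nephron epithelium apart from the duct it will join. The Notch target genes Hes5 and Hey1, which encode transcriptional repressors, were 85.1-fold and 57-fold higher in the renal vesicle (log2 differences 6.41, SE 0.23, and 5.83, SE 0.25, n = 3 arrays per structure). Lhx1, a homeobox gene required for nephron formation, was 44.4-fold higher (log2 difference 5.47, SE 0.24, adjusted p = 1.1e-08), and Wt1, the Wilms tumour gene, was 61.8-fold higher (5.95, SE 0.29, adjusted p = 2.9e-08). In the other direction Foxa1, a forkhead factor of epithelia, was 132-fold lower (log2 difference -7.04, SE 0.23, adjusted p = 1.3e-09). The keratin gene Krt19 was 112-fold lower (-6.81, SE 0.40, adjusted p = 1.7e-07), falling from a collecting duct level of 12.77 ± 0.29 to 5.96 ± 0.77 (log2, SD, n = 3).

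In total 2519 genes differed between renal vesicle and collecting duct, 1250 higher and 1269 lower in the renal vesicle. Median centring in place of quantile normalization gave 1560 higher and 1045 lower (59.9% higher), and no further normalization gave 1138 and 1447, so the balance of rises and falls depends on the scaling. With median centring the median difference of all genes was 0.11 here, against 0.01 with quantile normalization, and -0.11 against -0.03 for s-shaped body against renal vesicle. The 3 arrays of one structure all lay above those of the other for 43.3% of all genes, where chance gives 10%. Other strong rises were Lama4 (log2 difference 5.58, SE 0.18), a laminin chain, Nr2f1 (5.46, SE 0.17), an orphan nuclear receptor, and Aldh1a2 (5.19, SE 0.17), which makes retinoic acid. Hoxa9 rose by 6.69 (SE 0.35) with the brighter of its probe sets, whereas the other gave -0.76 (adjusted p = 0.031), so its direction rests on the probe set. Among the strong falls were Ctse (-5.69, SE 0.18), which encodes the protease cathepsin E, Lgals3 (-5.91, SE 0.23), which encodes galectin-3, and Trp63 (-4.75, SE 0.22), a p63 transcription factor of stratified epithelia.

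Genes of nephron induction rose as a group in the renal vesicle. Of 16 measured members 13 rose, 1 fell and 2 were not past the threshold, or 14 and 1 adjusted over the list alone, with a median of 2.51 (camera adjusted p = 7.7e-11, adjusted p = 0.016 with an estimated correlation). The Notch ligand genes Dll1 and Jag1 rose 7.99-fold (SE 0.18) and 8.78-fold (SE 0.28). Pax8, a paired-box gene of the nephron lineage, rose by 1.52 (SE 0.20, adjusted p = 0.00013). Wnt4, the signal that drives the mesenchyme to epithelium, was bright in both structures (11.19 ± 0.06 and 10.51 ± 0.40) and its difference of 0.68 did not pass (adjusted p = 0.095). It did pass without collecting duct replicate 3 (0.88, adjusted p = 0.038) or without s-shaped body replicate 1 (0.68, adjusted p = 0.031). Genes of the cap mesenchyme, from which the vesicle forms, rose in 7 of 10 cases and fell in 1, or 8 and 1 adjusted over the list alone (median 2.11, camera adjusted p = 3.2e-05, adjusted p = 0.043 with an estimated correlation). Uncx, a homeobox gene, was 30.4-fold higher (SE 0.25), Hoxa10 17.2-fold (SE 0.16) and Six2, the nephron progenitor regulator, 2.17-fold (log2 difference 1.12, SE 0.23, adjusted p = 0.0031). The 14 measured interstitium genes moved as well, with 8 rises and 1 fall (8 and 1 adjusted over the list alone, camera adjusted p = 0.00043, adjusted p = 0.13 with an estimated correlation), so stromal transcripts accompanied the mesenchymal ones.

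Proliferation genes were higher in the renal vesicle than in the collecting duct. Of 29 measured cell cycle genes 22 rose and 0 fell, or 25 and 0 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.1e-08, adjusted p = 0.056 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, rose by 1.22 (SE 0.11) and the replication helicase gene Mcm7 by 1.13 (SE 0.13). The ureteric tip list had 5 rises and 0 falls among 9, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0066, adjusted p = 0.22 with an estimated correlation). Its risers included Lhx1 (5.47, SE 0.24) and Ccnd1 (3.10, SE 0.17), which also stand in the nephron induction list, and Mycn (2.78, SE 0.19). The list's median of 1.55 dropped to 0.55 without renal vesicle replicate 1 (adjusted p = 0.066) and to 0.56 without replicate 2 (adjusted p = 0.078), where the call was lost. Lhx1, bright in the renal vesicle alone, fell below the intensity filter in both settings, so the list also shrank. Lhx1 was not tested without replicate 3 either, yet the call was kept there. The absence of Lhx1 alone therefore does not account for the lost calls, which depend on replicates 1 and 2. Notch pathway genes rose in 7 of 20 cases and fell in 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.15 with an estimated correlation, and adjusted p = 0.072 without renal vesicle replicate 3). Its risers Hes5, Hey1, Dll1 and Jag1 also stand in the nephron induction list. Hox genes rose in 8 of 18 cases and fell in 3, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.0043, adjusted p = 0.15 with an estimated correlation). Hoxd10, which like Hoxa10 also stands in the cap mesenchyme list, was 12.5-fold higher (SE 0.22).

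Collecting duct and urothelial genes fell. Of 28 trunk genes 22 were lower in the renal vesicle and 2 higher, the same counts adjusted over the list alone, with a median of -2.43 (camera adjusted p = 3.8e-13, adjusted p = 0.065 with an estimated correlation). Perp, a desmosome-associated gene, was 25.5-fold lower (SE 0.20) and the keratin partners Krt8 and Krt18 were 22.4-fold and 15.1-fold lower (SE 0.32 and 0.29). Calb1, a calcium-binding protein gene on the trunk list, was instead 32.3-fold higher in the renal vesicle (log2 difference 5.02, SE 0.85, adjusted p = 0.00072), with 12.6 and 13.18 in replicates 1 and 2 against 8.59 in replicate 3. Of 5 urothelium genes 4 fell and 0 rose, also adjusted over the list alone (median -3.39, camera adjusted p = 1.3e-05, adjusted p = 0.067 with an estimated correlation). The uroplakin gene Upk3a was 10.5-fold lower (SE 0.26). In the collecting duct arrays Trp63 and Foxa1, both on the urothelium list, stood at 11.29 and 13.42 and Upk3a at 9.31, while Aqp2 stood at 7.75. The reference samples thus held urothelial as well as trunk transcripts, and their source was not tested. Epithelial junction genes split into 17 falls and 7 rises of 29, the same adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.16 with an estimated correlation). The epithelial cadherin gene Cdh1 differed by -2.10 (SE 0.24) and the mesenchymal cadherin gene Cdh11 by 4.26 (SE 0.21). Glycolysis and hypoxia genes fell in 9 of 19 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.00054, adjusted p = 0.065 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase gene, fell by 2.82 (SE 0.19) and Bnip3 by 2.74 (SE 0.34). Immediate-early and stress genes were also lower in the renal vesicle, 18 of 22 with 0 rises, over the list alone as well as over all genes (median -1.78, camera adjusted p = 1.3e-11, adjusted p = 0.081 with an estimated correlation). Klf6 was 18.3-fold lower (SE 0.29), Hspa1b 10.6-fold (SE 0.32) and Fos 4.03-fold (SE 0.33). Higher stress transcripts accompanied the trunk genes of the collecting duct samples.

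Several anchor genes and lists stayed short of a call in this comparison. Podxl, the podocyte sialoprotein gene, differed by 1.78 (SE 0.66, adjusted p = 0.058), with replicate 3 at 11.54 and the others at 8.22 and 8.16. It passed at 0.66 (adjusted p = 0.011) without replicate 3, at 2.31 (adjusted p = 0.029) without replicate 1 and at 2.35 (adjusted p = 0.023) without replicate 2. Nphs1, which encodes nephrin of the slit diaphragm, did not pass (-0.08, adjusted p = 0.86), nor did Hoxb7 (-0.35, adjusted p = 0.27) or the water channel gene Aqp2 (-0.10, adjusted p = 0.81). The neural genes Th (-0.29, adjusted p = 0.37) and Dcx (0.22, adjusted p = 0.47) did not pass, nor did the sex-linked genes Xist (-0.12, adjusted p = 0.81), Eif2s3y (-0.29, adjusted p = 0.61), Kdm5d (-0.15, adjusted p = 0.73) and Uty (-0.26, adjusted p = 0.59). The podocyte list passed with 7 rises and 2 falls of 17, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.019, adjusted p = 0.43 with an estimated correlation), but not without renal vesicle replicate 3 (adjusted p = 0.068). Of 6 loop and distal tubule genes 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.24 with an estimated correlation). Leaving out an array ended this call for renal vesicle replicate 1 (adjusted p = 0.10), replicate 2 (adjusted p = 0.25) or replicate 3 (adjusted p = 0.28), or collecting duct replicate 1 (adjusted p = 0.053). Endothelium (3 rises, 2 falls, adjusted p = 0.27), erythroid (1 rise, 0 falls, adjusted p = 0.22), proximal tubule (3 and 2, adjusted p = 0.30), basement membrane (8 and 7, adjusted p = 0.28), Wnt signalling (8 and 5, adjusted p = 0.52), FGF and RET response (4 and 3, adjusted p = 0.98) and BMP and TGF-beta signalling (4 and 6, adjusted p = 0.66) did not pass as lists. Adjusted over the list alone their rises and falls were 3 and 2, 0 and 0, 6 and 2, 8 and 7, 8 and 5, 4 and 4, and 5 and 6. The median and the mean had opposite signs for Wnt signalling (-0.01 and 0.16) and for FGF and RET response (-0.26 and 0.16).

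The comparison of s-shaped body with collecting duct asks what the folded nephron expresses that the duct does not. Podxl, the major sialoprotein of the podocyte surface, was 120-fold higher in the s-shaped body (log2 difference 6.90, SE 0.66, n = 3 arrays per structure), reaching 14.43 ± 0.02. Ptpro, a receptor phosphatase of podocytes, was 162-fold higher (7.34, SE 0.72) and Wt1 137-fold (7.09, SE 0.29, adjusted p = 5.3e-09). Cldn5, a claudin of endothelium and podocytes, was 285-fold higher (8.15, SE 0.33, adjusted p = 5.3e-09). Foxa1 was 193-fold lower (-7.60, SE 0.23), Krt19 120-fold lower (-6.90, SE 0.40) and the epithelial cadherin gene Cdh1 53.3-fold lower (-5.74, SE 0.24).

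A total of 2626 genes differed between s-shaped body and collecting duct, 1355 higher and 1271 lower in the s-shaped body. The groups did not overlap for 43.9% of all genes, where chance gives 10%. Other strong rises were Enpep, which encodes aminopeptidase A (102-fold, SE 0.27), and Cxcl12, a chemokine gene (88.2-fold, SE 0.24). Gimap4, a GTPase gene known from lymphocytes, rose 119-fold (SE 0.35), and the endothelial adhesion gene Icam2 102-fold (SE 0.35). The embryonic globin gene Hbb-y rose by 7.29 (SE 1.32, adjusted p = 0.00097). Without collecting duct replicate 2, the array of the duct with bright Hbb-y, the rise was 9.46 (adjusted p = 1e-06), against 6.25 without replicate 1 and 6.24 without replicate 3. Among the falls were Plet1 (-6.30, SE 0.24), an epithelial surface protein gene, and Epcam (-5.93, SE 0.29), the epithelial adhesion molecule gene.

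Podocyte genes rose together. Of 17 measured members 15 rose and 0 fell, also adjusted over the list alone, with a median of 3.38 (camera adjusted p = 5.3e-13, adjusted p = 0.070 with an estimated correlation). Tcf21, a transcription factor of glomerular development, was 77.6-fold higher (SE 0.38), Foxc2 51.6-fold (SE 0.20) and Nphs1 10.4-fold (SE 0.27, adjusted p = 9.7e-07). Basement membrane genes rose in 8 of 20 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.15 with an estimated correlation). The nidogen genes Nid1 and Nid2 were 42-fold and 17.2-fold higher (SE 0.19 and 0.16). Notch pathway genes rose in 9 of 20 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.13 with an estimated correlation). Hey1 was 29.8-fold higher (SE 0.25). Other risers of the list included Notch4 (2.18, SE 0.22), Dll4 (1.40, SE 0.26) and Mfng (1.75, SE 0.24), in arrays in which all 16 endothelium genes rose. With no filter, where another probe set stood for the gene, the Notch4 call was lost (0.33, adjusted p = 0.25). Nephron induction genes rose in 9 of 16 cases and fell in 1, or 9 and 2 adjusted over the list alone (median 0.89, camera adjusted p = 0.0020, adjusted p = 0.064 with an estimated correlation). Bmp7, a growth factor gene, was 5.82-fold higher (SE 0.18) and Wnt4 18.2-fold lower (SE 0.29). Cap mesenchyme genes rose in 6 of 10 cases and fell in 1, also adjusted over the list alone (median 1.15, camera adjusted p = 0.0056, adjusted p = 0.072 with an estimated correlation).

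Trunk genes were lower in the s-shaped body in 24 of 28 cases and higher in 0, also adjusted over the list alone (median -2.27, camera adjusted p = 4.4e-15, adjusted p = 0.059 with an estimated correlation). Krt8 was 85.5-fold lower (SE 0.32) and Krt18 63.6-fold (SE 0.29). Urothelium genes fell in 4 of 5 cases and rose in 0, also adjusted over the list alone (median -3.97, camera adjusted p = 5.2e-05, adjusted p = 0.072 with an estimated correlation). Trp63 was 37.3-fold lower (SE 0.22). Epithelial junction genes fell in 18 of 29 cases and rose in 7, also adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.15 with an estimated correlation). The desmoglein gene Dsg2 was 28.9-fold lower (SE 0.19). Glycolysis and hypoxia genes fell in 11 of 19 cases and rose in 4, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.14 with an estimated correlation). Hk2, a hexokinase gene, fell by 1.94 (SE 0.19) and Vegfa, the vascular growth factor gene, rose by 2.19 (SE 0.18). Wnt signalling genes fell in 6 of 20 cases and rose in 1, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.16 with an estimated correlation). Wnt7b, a ureteric bud signal, was 4.4-fold lower (SE 0.18). Immediate-early and stress genes fell in 13 of 22 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 8.9e-06, adjusted p = 0.16 with an estimated correlation). Egr2 fell by 3.86 (SE 0.23), beside these falls of duct genes.

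Genes of vessels and stroma were far higher in the s-shaped body samples, alongside the podocyte, basement membrane and Notch pathway genes, while blood genes did not all rise. All 16 measured endothelium genes rose, also adjusted over the list alone (median 2.99, camera adjusted p = 2e-15, adjusted p = 0.016 with an estimated correlation). Kdr, the main VEGF receptor gene, was 21.5-fold higher (SE 0.18) and Sox17, a vascular transcription factor gene, 41.2-fold (SE 0.23). All 14 interstitium genes rose, also adjusted over the list alone (median 4.44, camera adjusted p = 4.7e-13, adjusted p = 0.043 with an estimated correlation). The collagen gene Col1a2 was 72-fold higher (SE 0.34) and Foxd1, a stromal transcription factor gene, 34.5-fold (SE 0.37). Erythroid genes rose in 5 of 7 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.15 with an estimated correlation). The erythroid call was lost without s-shaped body replicate 1 (adjusted p = 0.20), replicate 2 (adjusted p = 0.17) or replicate 3 (adjusted p = 0.16). In each of these settings only 8 of 11 erythroid and macrophage genes still passed the filter, which needs 3 bright arrays. The losses therefore single out no array. The erythrocyte anion exchanger gene Slc4a1 was 41.6-fold higher (SE 0.37), while the transferrin receptor gene Tfrc was 4.13-fold lower (SE 0.24). Of the macrophage genes Csf1r was 8.81-fold higher (SE 0.24), whereas Adgre1 did not pass (0.19, adjusted p = 0.48).

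The remaining lists did not pass for s-shaped body against collecting duct. Cell cycle genes had 0 rises and 2 falls among 29 (adjusted p = 0.98), or 0 and 1 adjusted over the list alone, with a median of 0.02 and a mean of -0.01. Hox genes had 8 rises and 7 falls (adjusted p = 0.28), ureteric tip 2 and 5 (adjusted p = 0.66), proximal tubule 4 and 1 (adjusted p = 0.17), loop and distal tubule 3 and 1 (adjusted p = 0.27), FGF and RET response 1 and 5 (adjusted p = 0.30) and BMP and TGF-beta signalling 3 and 6 (adjusted p = 0.24). Each of these counts was the same adjusted over the list alone. Hoxa9, with its brighter probe set, was 79.4-fold higher (SE 0.35), and Pax8 did not differ detectably (0.06, adjusted p = 0.85). Gata3, a duct transcription factor gene, did not pass (-0.97, adjusted p = 0.12), although it did without renal vesicle replicate 2 (-0.97, adjusted p = 0.015).

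**Figure D2:**
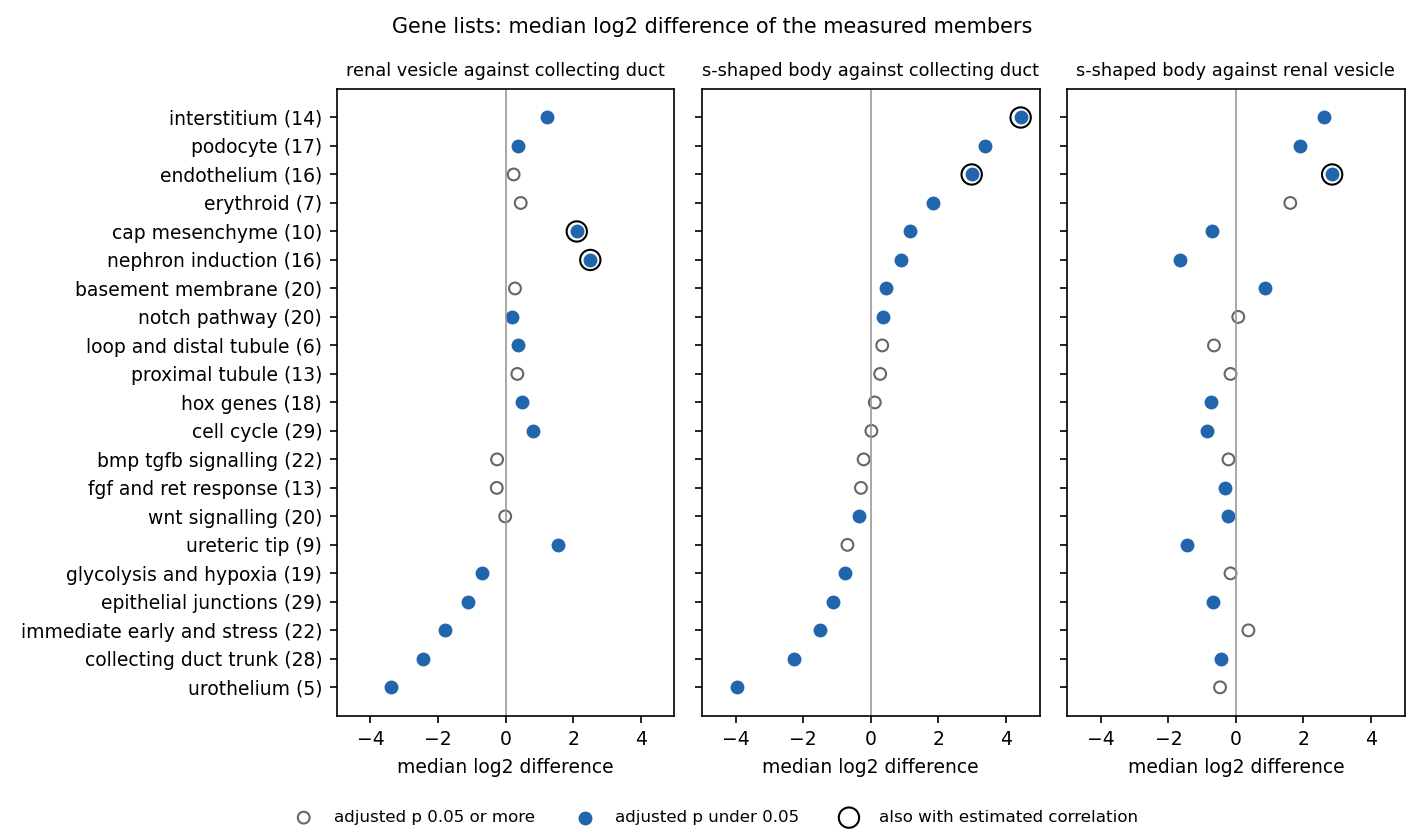
Median log2 difference of the measured members of each gene list in the 3 comparisons, with 1 point per list and comparison, filled where the camera adjusted p was under 0.05 and ringed where it was also under 0.05 with an estimated correlation. Endothelium and interstitium genes stand at 2.99 and 4.44 for s-shaped body against collecting duct, and collecting duct trunk genes at -2.43 and -2.27 for the nephron structures against the duct.

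The comparison of s-shaped body with renal vesicle sets samples of the folded stage against samples of the first nephron epithelium. Among podocyte genes Synpo, which encodes the actin-associated synaptopodin, was 35.7-fold higher in the later stage (log2 difference 5.16, SE 0.41, n = 3 arrays per structure) and the cell cycle inhibitor gene Cdkn1c 23-fold (4.53, SE 0.30, adjusted p = 5.9e-07). Among induction genes Hes5 was 37-fold lower (log2 difference -5.21, SE 0.23), Wnt4 29-fold lower (-4.86, SE 0.29) and Lhx1 17.3-fold lower (-4.12, SE 0.24, adjusted p = 2.7e-07). Epcam and Cdh1, genes of epithelial adhesion, were 12.7-fold and 12.4-fold lower (SE 0.29 and 0.24). They stood at only 5.94 and 6.18 in the s-shaped body, where Podxl stood at 14.43. Whether such falls reflect the stage or the cell make-up of the dissected samples was not tested. The vascular gene Sox17 was 74.5-fold higher (6.22, SE 0.23, adjusted p = 2.6e-08).

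In total 2905 genes differed between s-shaped body and renal vesicle, 1482 higher and 1423 lower in the s-shaped body, and the groups did not overlap for 52.9% of all genes, where chance gives 10%. The balance turned with the scaling, at 1307 higher and 1688 lower with median centring and 1631 and 1280 with no further normalization. The sizes of 3 named podocyte differences depended on single renal vesicle arrays, mostly replicate 3. Podxl rose by 5.12 (SE 0.66, adjusted p = 8.6e-05) with it and by 6.19 (adjusted p = 3e-09) without it, Ptpro by 5.26 (SE 0.72) and 6.40, and Synpo by 5.77 without it. Ptpro rose by 4.58 without renal vesicle replicate 1. Other rises were Tm4sf1 (75.9-fold, SE 0.33), Mef2c (39.2-fold, SE 0.25), a transcription factor gene of muscle and endothelium, and Igfbp3 (45.6-fold, SE 0.30). Falls included Gldc, which encodes a glycine-cleaving enzyme (21.4-fold, SE 0.22), Uncx (21.1-fold, SE 0.25) and Bex1 (20-fold, SE 0.28).

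Of 17 podocyte genes 15 rose from renal vesicle to s-shaped body and 0 fell, also adjusted over the list alone (median 1.89, camera adjusted p = 5.5e-10, adjusted p = 0.093 with an estimated correlation). In the same arrays 16 of 16 endothelium and 13 of 14 interstitium genes rose. Nphs1 rose by 3.46 (SE 0.27, adjusted p = 1.9e-06) and Wt1, already bright in the renal vesicle, by 1.15 (SE 0.29, adjusted p = 0.0082). Nephron induction genes fell in 11 of 16 cases and rose in 4, also adjusted over the list alone (median -1.66, camera adjusted p = 0.00024, adjusted p = 0.055 with an estimated correlation). Bmp2, a growth factor gene, fell by 3.23 (SE 0.21) and Pax8 by 1.46 (SE 0.20), while Bmp7 rose by 1.45 (SE 0.18). Cap mesenchyme genes fell in 6 of 10 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.072 with an estimated correlation). Without renal vesicle replicate 1 the cap mesenchyme call was lost (adjusted p = 0.071), as it was without replicate 2 (adjusted p = 0.076) or replicate 3 (adjusted p = 0.060). Its member Uncx, bright in the renal vesicle alone, falls below the intensity filter when any of these arrays is left out. The list then shrinks, so the losses single out no array. Ureteric tip genes fell in 6 of 9 cases and rose in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.12 with an estimated correlation). Myb fell by 3.20 (SE 0.27) and Wnt11 by 1.44 (SE 0.30).

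Cell cycle genes fell in 23 of 29 cases and rose in 0, or 24 and 0 adjusted over the list alone (median -0.85, camera adjusted p = 3.2e-08, adjusted p = 0.056 with an estimated correlation). Rrm2 fell by 1.30 (SE 0.11), Mcm7 by 1.12 (SE 0.13) and the replication licensing gene Cdc6 by 1.29 (SE 0.16). Hox genes fell in 10 of 18 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0093, adjusted p = 0.16 with an estimated correlation). Hoxd10 fell by 1.44 (SE 0.22). Wnt signalling genes fell in 9 of 20 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0055, adjusted p = 0.13 with an estimated correlation). Dkk1, a secreted inhibitor gene, fell by 2.52 (SE 0.20). FGF and RET response genes fell in 6 of 13 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.040, adjusted p = 0.14 with an estimated correlation). This FGF and RET call was lost without renal vesicle replicate 1 (adjusted p = 0.079) or 2 (adjusted p = 0.11) and without s-shaped body replicate 2 (adjusted p = 0.054) or 3 (adjusted p = 0.054). Collecting duct trunk genes fell in 11 of 28 cases and rose in 3, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.43 with an estimated correlation). The trunk call was lost without renal vesicle replicate 2 (adjusted p = 0.11), s-shaped body replicate 3 (adjusted p = 0.054), collecting duct replicate 1 (adjusted p = 0.063) or collecting duct replicate 3 (adjusted p = 0.075). Epithelial junction genes fell in 15 of 29 cases and rose in 6, also adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.26 with an estimated correlation). Without collecting duct replicate 3 they did not pass (adjusted p = 0.060). These falls, like those of the induction genes, were measured in arrays in which 16 of 16 endothelium and 13 of 14 interstitium genes rose and whose Gapdh 3'/5' ratio (20.0 to 32.4) lay above that of every renal vesicle array.

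Basement membrane genes rose in 11 of 20 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.0055, adjusted p = 0.16 with an estimated correlation). The laminin gene Lama1 fell by 3.10 (SE 0.26), whereas Nid1 rose by 2.69 (SE 0.19) and the collagen gene Col18a1 by 2.18 (SE 0.18). These rises came with those of vascular and stromal genes in the same arrays. All 16 endothelium genes rose, also adjusted over the list alone (median 2.85, camera adjusted p = 2.4e-14, adjusted p = 0.016 with an estimated correlation). Kdr was 18-fold higher (SE 0.18). Cldn5, the member that the epithelial junction list also holds, stood at 12.39 in the renal vesicle and rose by 1.64 (SE 0.33). Interstitium genes rose in 13 of 14 cases and fell in 0, also adjusted over the list alone (median 2.62, camera adjusted p = 2.7e-09, adjusted p = 0.056 with an estimated correlation). The smooth muscle actin gene Acta2 was 8-fold higher (SE 0.17). Of the macrophage genes Csf1r rose by 3.42 (SE 0.24), Ctss by 1.89 (SE 0.31) and Laptm5 by 3.90 (SE 0.25). Erythroid genes rose in 5 of 7 cases and fell in 1, or 5 and 2 adjusted over the list alone. As a list they stayed short of the threshold (camera adjusted p = 0.056) but passed it without renal vesicle replicate 2 (adjusted p = 0.027) or collecting duct replicate 2 (adjusted p = 0.029). Hbb-y rose by 4.22 (SE 1.32, adjusted p = 0.025). That call was lost without renal vesicle replicate 1 (4.43, adjusted p = 0.052), renal vesicle replicate 3 (3.45, adjusted p = 0.086), or s-shaped body replicate 1 (4.19, adjusted p = 0.070), 2 (4.26, adjusted p = 0.065) or 3 (4.22, adjusted p = 0.070).

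The other lists did not pass for s-shaped body against renal vesicle. Immediate-early and stress genes had 8 rises and 1 fall among 22, also adjusted over the list alone (camera adjusted p = 0.056), and passed without renal vesicle replicate 1 (adjusted p = 0.040) or s-shaped body replicate 2 (adjusted p = 0.0093) or 3 (adjusted p = 0.041). Urothelium had 1 rise and 0 falls (adjusted p = 0.71), proximal tubule 4 and 1 (adjusted p = 0.68), and loop and distal tubule 2 and 3 (adjusted p = 0.39), the same counts adjusted over the list alone. Notch pathway genes had 3 rises and 5 falls, or 4 and 6 adjusted over the list alone (adjusted p = 0.80), BMP and TGF-beta signalling 2 and 6, or 2 and 8 adjusted over the list alone (adjusted p = 0.22), and glycolysis and hypoxia 6 and 3, or 7 and 5 adjusted over the list alone (adjusted p = 0.84). The median and the direction of the test differed for Notch (0.07, down), proximal tubule (-0.16, up) and glycolysis and hypoxia (-0.16, up).

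**Figure D3:**
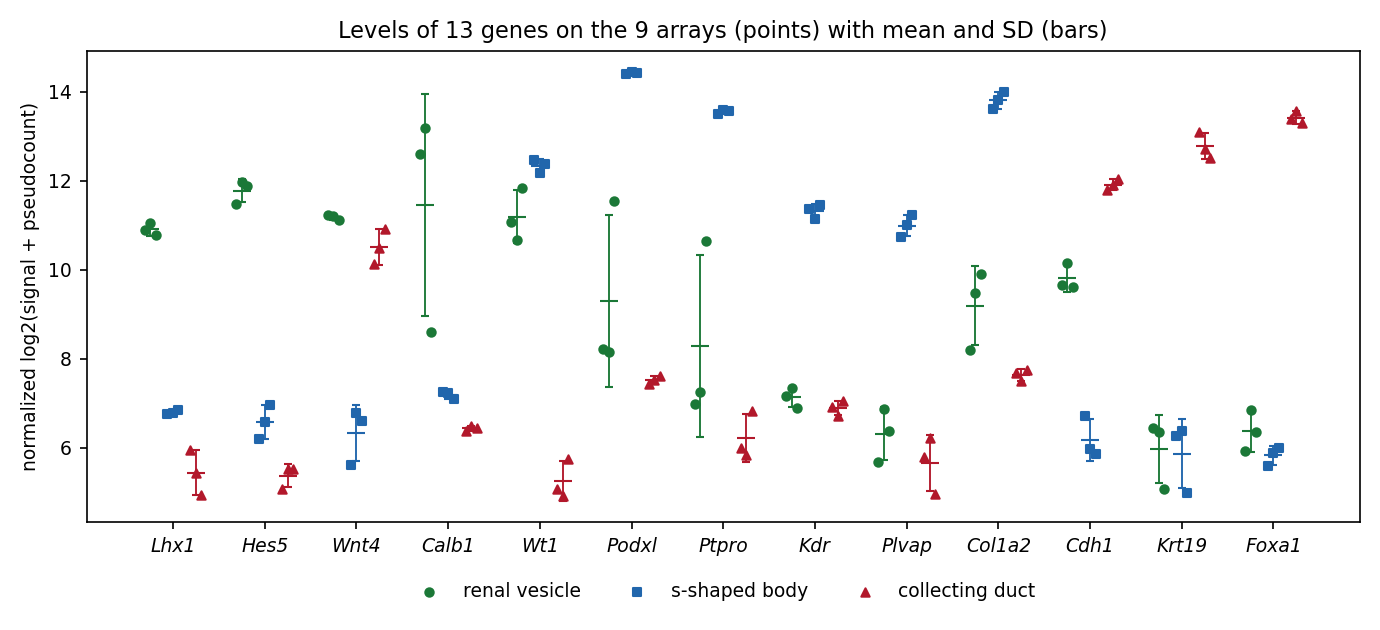
Log2 intensity of named genes on each of the 9 arrays, with 1 point per array and bars for the mean and SD of each structure. Podxl reaches 14.43 in the s-shaped body and Foxa1 13.42 in the collecting duct, and renal vesicle replicate 3 stands apart for Podxl.

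Genes higher in 1 structure than in each of the others numbered 656 for the renal vesicle, 866 for the s-shaped body and 662 for the collecting duct. Hes5 (at least 5.21 log2 units above either other structure), Uncx (4.40), Calb1 (4.26, with replicate 3 far below the others) and Lhx1 (4.12) led the renal vesicle set, Gimap4 (6.39) and Tm4sf1 (6.25) the s-shaped body set, and Foxa1 (7.04) and Krt19 (6.81) the collecting duct set. The counts depend on single arrays, since leaving out renal vesicle replicate 1 or 2 gave 394 or 390 genes for the renal vesicle. Leaving out s-shaped body replicate 2 or 3 gave 540 or 543 for the s-shaped body, and leaving out collecting duct replicate 2 gave 420 for the collecting duct.

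Both nephron structures differed from the collecting duct in the same direction for 1151 genes, 489 higher and 662 lower. By definition the 662 lower genes are the collecting duct enriched genes counted above, so they are no separate result. Foxa1, Krt19 and Trp63 were lower in both, and Wt1, Hey1 and Foxc2 were higher in both. Independent calls would share 212 and 202 genes, and 158 genes were called in opposite directions. The fold changes had a covariance of 0.61 across genes, against a mean of 0.027 in 100 simulations without differences. In these all arrays were simulated with independent noise per gene, and both comparisons shared the simulated collecting duct arrays. The correlation of the fold changes across genes was 0.61, where sharing a simulated reference alone gave a mean of 0.50. The simulations cover only the noise of the shared arrays. Expression particular to the collecting duct would also enter both comparisons. Neither the overlap nor the covariance separates it from changes that the nephron structures share. With 3 collecting duct arrays the reference could not be split into separate parts of at least 2.

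Some anchor genes gave no comparison. Probe sets for Fgf8, Ret, Wnt9b, Cited1, Gdnf and Pecam1 fell below the intensity filter.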

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

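The comparisons behind these values were planned, and no further test was chosen here after the values were seen. Of the gene lists, 4 pointed in opposite directions in the nephron structures against the collecting duct and were then called in the direct comparison of s-shaped body with renal vesicle at the preset correlation. With an estimated correlation none of these 4 direct calls held (adjusted p = 0.12 for ureteric tip, 0.056 for cell cycle, 0.13 for Wnt signalling and 0.14 for FGF and RET response). The ureteric tip genes had a median of 1.55 in the renal vesicle and -0.69 in the s-shaped body against the duct, and -1.44 directly. The renal vesicle median was 0.55 (adjusted p = 0.066) without renal vesicle replicate 1 and 0.56 (adjusted p = 0.078) without replicate 2, with Lhx1 below the intensity filter in both settings. The call against the duct was kept without replicate 3, where Lhx1 was not tested either. Cell cycle genes had 0.80 against the duct in the renal vesicle and 0.02 with a negative mean in the s-shaped body, and -0.85 directly. Wnt signalling genes had -0.24 directly and FGF and RET response genes -0.31, with medians against the duct that were negative in both structures while the tests of the renal vesicle, which did not pass, pointed up. The direct FGF and RET call was lost without renal vesicle replicate 1 (adjusted p = 0.079) or 2 (adjusted p = 0.11) and without s-shaped body replicate 2 (adjusted p = 0.054) or 3 (adjusted p = 0.054).

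Single genes also went opposite ways against the collecting duct, 71 of them higher in the renal vesicle and lower in the s-shaped body, and 87 the reverse. Tgfbr2, a TGF-beta receptor gene, was lower in the renal vesicle (-1.01) and higher in the s-shaped body (1.43), a direct difference of 2.44 (SE 0.17, adjusted p = 7.6e-07). Postn, a matrix gene of the interstitium list, did the same (-2.07 and 1.92, direct difference 3.98, adjusted p = 5.5e-06).

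Probe sets with no gene name or with several were left out of the comparisons, and 993 of them passed the same intensity filter. Among these 193 differed between renal vesicle and collecting duct, 204 between s-shaped body and collecting duct, and 286 between s-shaped body and renal vesicle, which is 19.4%, 20.5% and 28.8%. No explanation was tested for them.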

How the results depend on the processing

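All alternatives were planned except replicate 3 as a batch and the joint omission of renal vesicle replicate 3 and collecting duct replicate 2, which were chosen after seeing the data. The spike-in signal was highest in replicate 3 of each structure, which bears on the batch and not on the joint omission. Of 211 counts under alternatives 188 stayed within 1.5 times the reported count and 23 did not. Of 5861 values of named genes 5744 kept their side of the threshold, 71 lost and 46 gained a call, and 0 changed direction with a call in either setting. Of 1545 list tests 1433 kept their side, 81 lost and 31 gained a call, and 0 changed direction with a call in either setting. Changes of direction without any call were not counted.

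A filter at the 75th percentile, which tests fewer genes, gave 1648 genes for s-shaped body against collecting duct, 2613 for any structure, 433 for collecting duct enriched and 749 shared. Array weights gave 4747 for renal vesicle and 4508 for s-shaped body against collecting duct, 6119 for any structure, 1192 and 1268 for renal vesicle and collecting duct enriched, and 2340 shared, and the cause was not tested. Without both renal vesicle replicate 3 and collecting duct replicate 2, so with fewer arrays, the counts were 1542 for renal vesicle against collecting duct, 371 and 392 for renal vesicle and collecting duct enriched, and 715 shared. A 2-fold minimum left 1211, 1424 and 1379 genes. An estimated inter-gene correlation left 5 lists of 41, which were nephron induction and cap mesenchyme for renal vesicle against collecting duct, interstitium and endothelium for s-shaped body against collecting duct, and endothelium for s-shaped body against renal vesicle, while fry passed 55.

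Leaving out each array in turn gave 1837 to 2501 genes for renal vesicle against collecting duct, 1918 to 2704 for s-shaped body against collecting duct, 2131 to 3401 for s-shaped body against renal vesicle and 3223 to 4238 for any structure. Enriched genes ranged from 390 to 693 for the renal vesicle, 540 to 940 for the s-shaped body and 420 to 610 for the collecting duct, lists from 37 to 40, and shared changes from 809 to 1122. The filter needs 3 bright arrays, so genes bright in 1 structure alone, such as Hes5, Lhx1, Foxa1 and Krt19, were not tested when one of its arrays was left out, and 43 of 266 pairs of named gene and comparison lacked a value under at least 1 omission.

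Replicate numbers were not taken as pairs, since same-number deviations correlated at -0.03 to 0.16 across genes, and the number as a block gave 2605, 2646 and 2997 genes. The replicate 3 arrays correlated at 0.12 to 0.13, which leaves a batch open, and replicate 3 as a batch gave 2790, 2838 and 3155. Without detection calls, signal over background limits dim genes, whose differences the pseudocount shrinks.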

Other observations

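Each test of an explanation below and the 6 added gene lists were chosen after the results were seen, whereas the splits of the arrays in the last paragraph were planned. Epithelial regulators, a list of 17 genes of tight epithelium, fell in 16 cases in the renal vesicle and in 16 in the s-shaped body against the collecting duct (medians -2.40 and -3.65). The list holds genes picked from the strongest falls, such as Epcam, so no test of it is given. The differences were -4.27 and -5.12 for Tmprss2, a membrane protease gene, -3.16 and -3.02 for the splicing regulator gene Esrp2, and -2.67 and -4.05 for the matriptase inhibitor gene Spint1. Zeb1, a repressor of epithelial genes, was the exception and rose by 2.54 and 5.39. In these comparisons 8 and 14 of the 14 interstitium genes rose, and 18 and 13 of the 22 immediate-early and stress genes were lower than in the duct. Between renal vesicle and s-shaped body 12 of the 17 fell and Zeb1 rose by 2.85 (list median -1.12), in arrays whose stromal genes also rose.

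Imprinted genes were higher in the s-shaped body than in the renal vesicle in 10 of 15 cases, with 0 lower (median 0.70, camera adjusted p = 0.00024, and 0.028 with an estimated correlation). These p-values were adjusted over the added lists only. The list was written after the results were seen and holds Cdkn1c, already named among the rises of this comparison, so they are descriptive. Cdkn1c, which the podocyte list also holds, rose by 4.53, Mest by 1.34, Plagl1 by 1.70 and Meg3 by 1.73, while Igf2 stood at 12.28 and 12.34. In the same arrays 13 of 14 interstitium and 16 of 16 endothelium genes rose. Against the collecting duct the list did not pass (adjusted p = 0.38 for the renal vesicle and 0.15 for the s-shaped body). Mitochondrial respiration genes, 31 in all, had 0 rises and 1 fall in the renal vesicle and 1 of each in the s-shaped body against the duct (adjusted p = 0.71 and 0.93), and 0 and 1 directly (adjusted p = 0.69). Retinoic acid (adjusted p = 0.10, 0.13 and 0.89 for renal vesicle and s-shaped body against the duct and for the direct comparison), guidance cues (0.86, 0.43 and 0.26) and cystic disease genes (0.43, 0.26 and 0.68) did not pass.

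Vascular and stromal genes and most blood genes were higher in the s-shaped body arrays, with all 16 endothelium genes above the renal vesicle. Array scaling is argued against, since the endothelium median was 2.83 at the lowest and 2.98 at the highest of 3 normalizations. Carry-over of kidney tissue that includes collecting duct is argued against as the source of these genes, since 21 trunk genes dim in the renal vesicle had a median difference of -0.40, with 2 rises and 6 falls and an upper quartile of 0.14. Part of the falls reflects the baseline, as Cldn8 stood at 8.76 and 9.43 in renal vesicle replicates 1 and 2 against 5.37 in replicate 3. At 5.52 in the s-shaped body Cldn8 lay near replicate 3, but a median over the trunk genes against replicate 3 alone was not computed. Krt19 stood at 5.87 in the s-shaped body and 12.77 in the duct, although Krt7 (2.97) and Gata3 (1.86, and 2.50 without renal vesicle replicate 2) rose, which leaves some tissue of this kind open. Vascular, blood and stromal cells in or on the dissected structures would raise blood genes too. Of 11 erythroid and macrophage genes 9 rose (81.8%), with Csf1r at 11.55 and Slc4a1 at 11.16. Without renal vesicle replicate 1 there were 7 calls of 11, although 9 of the 11 still lay higher. The calls of Hbb-y (adjusted p = 0.052) and Adgre1 (adjusted p = 0.061) were lost there, with differences of 4.43 and 0.59 against 4.22 and 0.66 with all arrays. Without s-shaped body replicate 1 there were 4 calls among the 8 genes still tested, of which 6 lay higher. Tfrc fell by 1.66, Epor did not pass and the erythroid list alone stayed short of the threshold (adjusted p = 0.056). Such cells therefore remain possible, and whether they would be capillaries growing into the s-shaped body or adhering tissue stays open, although the submitters describe staining and RT-PCR to exclude other tissues.

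Renal vesicle replicate 3 stood apart from replicates 1 and 2, with 79 genes more than 2-fold above both and 95 more than 2-fold below both, among them 6 podocyte genes above. RNA with the make-up of the s-shaped body samples, vascular genes included, is argued against by the medians. Podocyte genes gained a median of 12.4% of their s-shaped body signal (8 genes) and endothelium genes -0.93% (12 genes, exact rank-sum p = 0.0011 across genes). That p compares genes of a single array in which podocyte genes had already been seen to be high. It measures no spread between samples. Against the argument, Cldn5 gained 37.3% and 9 interstitium genes a median of 3.25%, with Foxd1 at 22%. Collecting duct tissue in replicates 1 and 2 is argued against as the whole cause, since 57 of the 95 lower genes (60%) had a collecting duct level above theirs, and for those 57 it remains open. Ureteric tip tissue in replicates 1 and 2 stays open, as 8 of 9 tip genes (88.9%) were lower in replicate 3, Wnt11 at 7.75 against 8.90 and 8.92, but 1 of them by over 2-fold, and 20 of 28 trunk genes were lower too, 8 of them by over 2-fold, so the tip is not singled out. RNA of s-shaped bodies free of vessels, and a later stage of the vesicles in replicate 3, also remain open without a test of their own. Of the 79 genes above both other replicates, 78 were also higher in the s-shaped body than in replicates 1 and 2, which either would give. Against them, nephron induction genes were lower in replicate 3 in 4 of 16 cases, 0 of them by over 2-fold.

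Xist, expressed from the inactive X chromosome of females, and Y-linked genes both gave signal on every array, at 10.35 to 11.71 for Xist and 7.64 to 9.0 for the mean of 3 Y-linked genes. Without detection calls their presence was not tested, and Uty was as low as 7.01 on collecting duct replicate 3. Over the 9 arrays they were inversely related (Pearson r = -0.85, exact permutation p = 0.0034, Spearman rho = -0.57, exact permutation p = 0.12, 1 relation computed), and the deviations from the structure means gave r = -0.91 (exact permutation p = 0.032 over 216 arrangements). Without the 2 farthest arrays r was -0.54 (exact permutation p = 0.19, 7 arrays), so the relation rests on those arrays as far as 7 arrays can test it, although r was negative within each of the 3 structures. RNA of male and female embryos in every sample, and probe sets that do not separate the sexes, cannot be told apart with that value. Collecting duct replicates 1 and 3, each with a pool size of 1, had Xist at 10.36 and 11.71 beside Y-linked means of 8.80 and 7.64, and the labels give neither the sex nor whether 1 means a single duct or the ducts of 1 kidney, which bears on whether RNA of both sexes can be in such a sample.

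Collecting duct arrays differed among themselves. Hbb-y stood at 11.20 in replicate 2 and at 4.78 and 4.93 in the others, and replicate 3 had 64 genes more than 2-fold above both others and 191 more than 2-fold below both.

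Other ways of splitting the arrays into groups of 3 gave fewer genes. For each pairwise comparison there are 10 splits of the 6 arrays, too few for a share under 0.05, and the real split, 1 of the 10, gave 2519, 2626 and 2905 genes while the highest other gave 0 in each. For the F test, 1 of 100 drawn splits, the real one, reached 3965 genes and the highest other 769, so chance can be excluded as the source of that count. The same holds for structure-enriched genes (at least 656 in the real split, 389 at most in another, 1 of 100). For list tests past the threshold the real split was also 1 of 100, but with 41 against 36 of 63 in another split the count separates poorly, and 5 held with an estimated correlation.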
